A study of Mus musculus with 7 samples.

How the data were processed

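RNA was measured in lineage-negative cells of mouse fetal liver at embryonic day 14.5, which is the main site of blood formation at that stage. Lineage-negative cells are the stem and progenitor fraction that remains after cells carrying markers of mature blood lineages are removed, here with magnetic beads. Per the labels' protocols, RNA was extracted on columns and polyA RNA libraries were made with the TruSeq Stranded mRNA kit. The mice were C57BL/6 with Brd9 alleles flanked by loxP sites, and the knockout embryos also carried Vav1-iCre, a recombinase active in blood cells. The labels give 3 control libraries without the recombinase and 4 knockout libraries with it. They do not say whether each library came from a separate embryo or from a pool, so p-values measure only the spread between these libraries, which may be partly technical.

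The deposited count table holds raw read counts per gene symbol, 1 column per library. Per the submitters' processing notes, reads were aligned with HISAT2 to mm10 and counted with featureCounts. Versions, the annotation, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. Genes that overlap others or have near-identical copies can therefore have lost or gained reads. The authors' deposited table of their own comparison holds log2 fold changes with standard errors, p-values and adjusted p-values from DESeq2, a test score, and a signal, counts divided by a size factor. In each library the ratio of count to deposited signal was 1 constant, between 0.855 and 1.14 over the 7 libraries. Of the 35976 symbols in the count table, 14 had been turned into dates and were read back as septin family symbols. Symbols were matched to the RefSeq annotation of GRCm38, the assembly that mm10 names, and 32501 of them matched. Coordinates are 1-based and come from that annotation.

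Total counts per library ran from 18748885 to 23571878, and 11634 symbols had no read in any library. Genes were kept with edgeR's filterByExpr, which left 14679. Counts were scaled by TMM and tested with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest, edgeR 4.0.16, R 4.3.3), with group as the only term and all 7 libraries in the fit. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Levels are CPM, each count as a share of the TMM-scaled library total, as mean ± SD, and log2 CPM used a prior count of 2. Brd9 was also tested with an exact permutation test over the 35 splits of 7 libraries into 3 and 4, two-sided, whose smallest possible p is 0.0286. On simulated counts with the means, depths and spread of these libraries, where the fit ran on 14450 genes, the test recovered 27.7% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 92.4% of those changed 4-fold. Of its calls there, 6.9% were unchanged genes. The simulation drew genes independently of each other and held no outlying library, so these shares can differ in the real data.

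Before the data were examined, 33 gene lists with 618 entries in all were written down: blood lineages and progenitors, other cell types the fraction could hold, Brd9's protein family, and stress and growth programmes. For 3 entries no row was found, and 15 were found under another symbol. Each list was tested with limma's camera (limma 3.58.1) with the inter-gene correlation preset at 0.01, two-sided, adjusted over the 33 lists. Camera asks whether the members stand apart from all other genes. Beside it stand camera with a correlation estimated for each list, limma's fry, which asks whether the members move one way on balance without comparing them with other genes, and an exact permutation test of each list's mean log2 CPM. Members were counted as risen or fallen with the adjustment over all genes and with the adjustment over the list alone. Some genes are in more than 1 list.

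The genes named are Brd9, the 10 with the largest fold change in each direction among changed genes with a mean of at least 1 CPM and no overlap between the groups, leaving out predicted genes, clone names and pseudogenes, and up to 4 members of each list with the smallest p. Only 1 gene qualified as higher. Sva, and any gene said to be chosen after its values were seen, fall outside that rule. Some genes are not reported here.

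Alternatives fixed beforehand were DESeq2 size factors or total counts for scaling, no filter or a minimum mean of 1 CPM, DESeq2 1.42.0, limma-voom, robust dispersion, a block on replicate number, 1 surrogate variable from sva 3.50.0, leaving out Xist, Tsix and the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d, and leaving out each library in turn. All other X-linked genes stayed in that fit without Xist, Tsix and the Y-linked genes. The level of Xist as a covariate and the permutation test of lists were added after the data were seen. Counts of libraries of the same group were compared with a chi-square test over genes. Its statistic per degree of freedom was between 9.16 and 46.3 over all pairs, where counts of 1 library split at random would give a value near 1, so no pair was treated as 1 library deposited more than once.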

Results

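The series profiled lineage-negative fetal liver cells from control embryos (Brd9fl/fl) and from embryos in which Vav1-iCre deletes Brd9 in blood cells. Brd9 is a bromodomain protein of the non-canonical BAF chromatin remodelling complex. There were 3 control and 4 knockout libraries, with 21865140, 23571878 and 21831430 counts in the controls and 18748885, 21861876, 21596964 and 20238810 in the knockouts. The design implies a single comparison, which asks which transcripts differ in fetal blood progenitors without Brd9. Every knockout library and no control carried Vav1-iCre, so effects of the recombinase itself cannot be told apart from those of Brd9 loss.

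Brd9 itself fell to 34.7% of control, from 33.0 ± 3.0 CPM (SD, n = 3) to 11.5 ± 2.0 CPM (SD, n = 4). The controls held 30.5, 32.2 and 36.4 CPM and the knockouts 8.57, 11.9, 13.2 and 12.2 CPM, so every library lay on the side its label gives. The log2 fold change was -1.53 (SE 0.15; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0037), and the exact permutation test gave p = 0.0286, the smallest it can give. Brd9 lies on the plus strand of chromosome 13 from 73937801 to 73960895 (GRCm38). These counts cover the whole gene, and the labels do not say which exons are flanked by loxP sites, so they do not measure how much intact transcript was left.

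The genes that fell in the knockouts included 8 of 19 tested members of the neutrophil list. Of 16 tested monocyte genes 1 fell, and of 16 tested mast cell, basophil and eosinophil genes 1. Camp, a cathelicidin stored in neutrophil granules, fell 39.5-fold from 179 ± 58 to 4.5 ± 3.0 CPM. Epx, the eosinophil peroxidase, fell 18.3-fold from 61.8 ± 22.3 to 3.38 ± 1.06 CPM, and F13a1, a coagulation factor subunit made by monocytes and platelets, fell 11.4-fold from 89.3 ± 24.3 to 7.81 ± 2.95 CPM (SD, n = 3 and 4). Gmpr, a guanosine monophosphate reductase, was 1.48-fold higher. In all, 82 of 14679 tested genes changed, of which 80 fell and 2 rose; leaving out single libraries gave between 20 and 120.

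**Figure D1:**
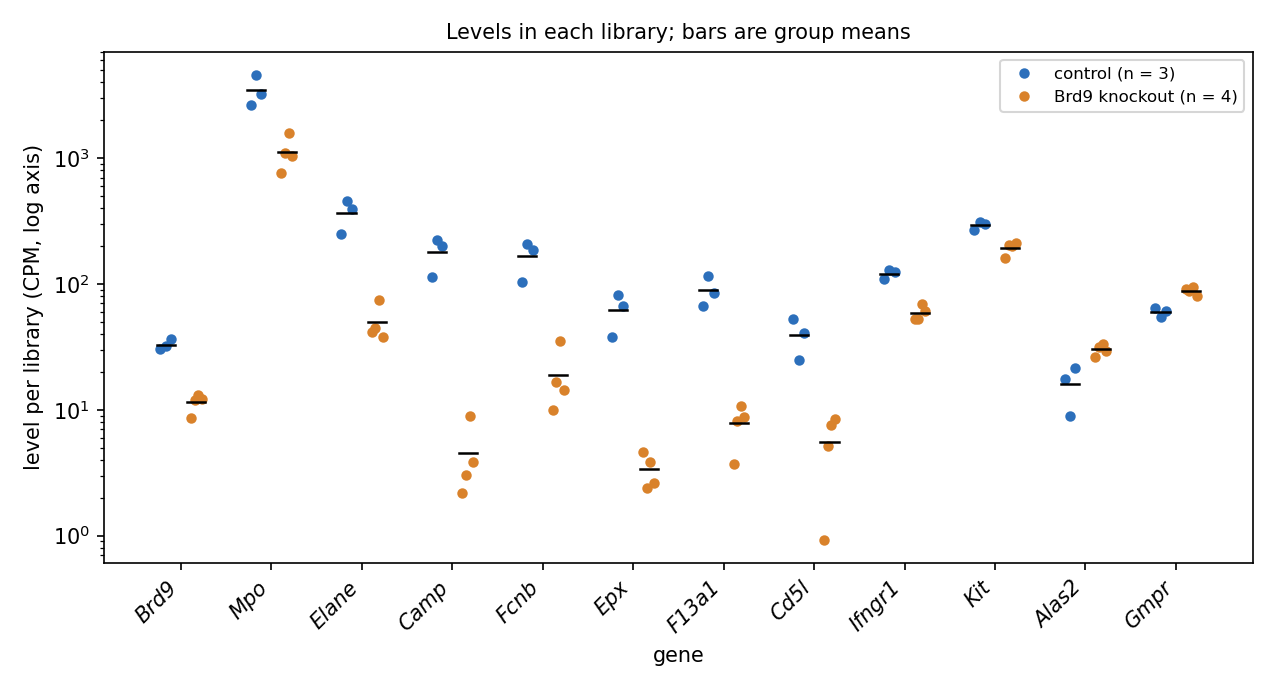
Level of 12 genes in each library, in CPM on a log axis. Blue points are the 3 control libraries, orange points the 4 knockout libraries, and black bars are group means. Camp lay between 114 and 225 CPM in the controls and between 2.18 and 8.94 CPM in the knockouts. Cd5l, Kit and Alas2 did not pass over all genes in edgeR.

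Among the 80 genes that fell, 64 did so at least 2-fold and 25 at least 4-fold. The largest fall was that of Serpinb10, a serine protease inhibitor of blood cells, with a log2 fold change of -5.99 (SE 0.44, adjusted p = 0.0013), from 12.0 ± 6.2 to 0.187 ± 0.075 CPM. It lies on chromosome 1 from 107528994 to 107560742. Camp (chromosome 9, 109847377 to 109849456) had a log2 fold change of -5.31 (SE 0.42, adjusted p = 0.0015) and Epx (chromosome 11, 87863997 to 87875536) of -4.20 (SE 0.30, adjusted p = 0.0013). The other genes of the 10 largest falls were Wfdc21 (-4.05), Siglec1, a sialic acid receptor of macrophages (-3.86), Kcna2, a potassium channel (-3.80), Chil3, a chitinase-like protein of myeloid cells (-3.61), F13a1 (-3.51), Nebl (-3.39) and Stfa3, a cysteine protease inhibitor (-3.27). Wfdc21, Siglec1, Kcna2 and Chil3 had control means of 4.90, 3.58, 2.27 and 3.46 CPM. Chil3 and Stfa3 belong to families of closely similar genes, whose reads the counting could have split. Kcna2 lost its call without any 1 of the 7 libraries, Chil3 without control replicate 2 or 3 or knockout replicate 1, 2 or 4, Wfdc21 without control replicate 3 or knockout replicate 2 or 4, and Siglec1 without control replicate 3. With the Xist level as a covariate Kcna2 (adjusted p = 0.135) and Chil3 (0.097) also lost their calls.

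In the other direction, Gmpr (chromosome 13, 45507428 to 45546386) rose from 59.9 ± 5.2 to 88.7 ± 6.5 CPM, a log2 fold change of 0.57 (SE 0.09, adjusted p = 0.030). That call was lost without control replicate 2 or 3 or knockout replicate 1 or 2, and with the Xist level as a covariate (adjusted p = 0.079), a setting chosen after the data were seen. The remaining gene, Sva (chromosome 6, 42038394 to 42042851), was chosen after its values were seen. It had no read in any control and between 21 and 33 reads in each knockout library, 107 in all. Taking 3 counts over the control group as the floor, it was at least 29.4-fold higher (adjusted p = 0.0082).

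**Figure D2:**
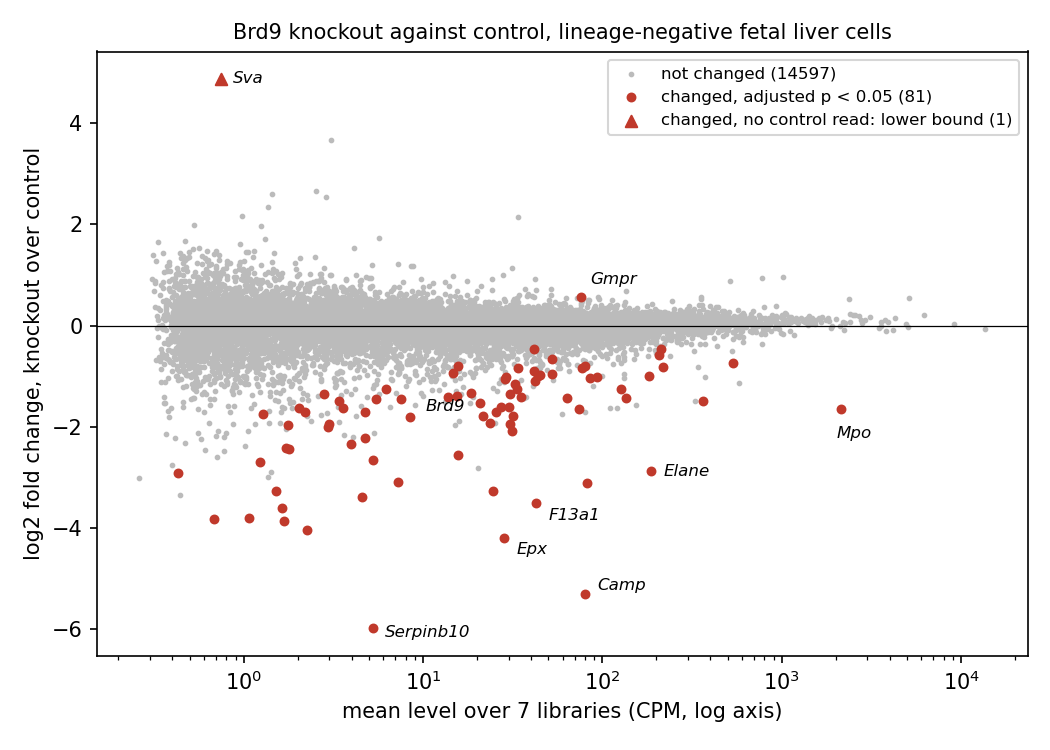
Log2 fold change of each tested gene, knockout over control, against its mean level over the 7 libraries in CPM on a log axis. Red points are genes at an adjusted p under 0.05, grey points all others. The triangle marks Sva at its lower bound. Nearly all red points lie below 0, from -0.46 for Spn to -5.99 for Serpinb10.

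The calls came from edgeR's quasi-likelihood test, and all 82 genes had no overlap between groups. Over all tested genes 11.2% had none, where chance gives 5.71%. At an unadjusted p under 0.05 there were 1593 genes, 580 higher and 1013 lower. The number of calls moved with the libraries used, to 49 without control replicate 2, 20 without control replicate 3, and 51, 21 and 37 without knockout replicate 1, 2 and 4. Where no member of a list passed over all genes in edgeR, the members at an unadjusted edgeR p under 0.05 and those that DESeq2 called are given beside it; limma-voom called 0 members of these 29 lists. The number of changed genes was 228 with no filter on low counts, 141 with 1 surrogate variable and 386 with DESeq2.

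The authors' deposited table of the same libraries lists 382 genes at an adjusted p under 0.05, 54 higher and 328 lower. It holds all 82 genes called here, with the same sign for all 82. It lists 292 further genes among those tested here, which all had the same sign and an unadjusted p under 0.05 in the edgeR test.

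Neutrophil genes formed the group with the most changed members. Of 19 tested members of the neutrophil list, 8 fell, 0 rose and 11 did not pass over all genes; adjusted over the list alone, 13 fell and 1 rose. The median log2 fold change was -1.19 and 18 of 19 members were lower. The list's mean log2 CPM was 5.94, 6.82 and 6.45 in the controls. It was 5.77 in knockout replicate 3, against 4.50, 4.88 and 4.87 in the other knockouts. In knockout replicate 3 the 8 members that fell and Csf3r lay below every control. Ltf (209 CPM), Lcn2 (127 CPM) and Mmp8 (3.36 CPM) stood above every control there. Ngp (160 CPM), Mmp9 (1.61 CPM) and the remaining members lay within the control range. These levels were compared after they were seen. Elane, the neutrophil elastase, fell 7.39-fold from 367 ± 106 to 49.7 ± 16.5 CPM, Fcnb, a ficolin, fell 8.71-fold, and Gfi1, a transcription factor needed for granulocyte formation, fell 3.07-fold from 44.4 ± 14.2 to 14.4 ± 1.8 CPM. Besides Camp, the members that fell also included Mpo, Prtn3, Ctsg and Ms4a3, chosen after their values were seen, with log2 fold changes of -1.64, -1.49, -1.44 and -1.42. Mpo, the myeloperoxidase of early granules, went from 3505 ± 998 to 1121 ± 348 CPM. Mmp8, the member that rose over the list alone and also chosen after its values were seen, had 0.463 CPM in the controls and 1.84 CPM in the knockouts. Camera gave an adjusted p = 4.9e-37 for the list, against an adjusted p = 0.493 with an estimated correlation. That estimate was 0.786, far above the preset 0.01. Mpo, Prtn3 and Ctsg lost their calls without control replicate 2 or 3 or knockout replicate 1, 2 or 4, Ms4a3 without the first 4 of these libraries, Fcnb without control replicate 3 or knockout replicate 2, and Gfi1 without knockout replicate 2. Elane and Camp were called in each fit that left out a library.

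Macrophage genes were lower in all 16 tested members, with a median log2 fold change of -0.98. None passed over all genes in edgeR, where 13 were lower at an unadjusted p under 0.05, while DESeq2 called 9 of them lower, among them Cd5l, Marco and Mrc1. Adjusted over the list alone, 12 fell in edgeR. Cd5l, a scavenger receptor family protein secreted by macrophages, had 39.5 ± 14.1 CPM in the controls and 5.55 ± 3.40 CPM in the knockouts (adjusted p = 0.054). Marco, a scavenger receptor, had 26.4 ± 8.3 and 6.71 ± 3.83 CPM, and Mrc1, the mannose receptor, 20.5 ± 3.0 and 12.7 ± 1.9 CPM. Camera gave an adjusted p = 2.5e-17, against an adjusted p = 0.498 with an estimated correlation.

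Of 16 tested monocyte genes, F13a1 fell and 15 did not pass; adjusted over the list alone, 2 fell and 0 rose. Ly6c2, a surface marker of inflammatory monocytes with a near-identical neighbour, had 27.1 ± 9.4 CPM in the controls and 7.29 ± 3.22 CPM in the knockouts (adjusted p = 0.055). The list had a median of -0.78 and a camera adjusted p = 2.0e-11, against an adjusted p = 0.714 with an estimated correlation. Of 16 tested mast cell, basophil and eosinophil genes, Epx fell and 15 did not pass; adjusted over the list alone, 3 fell and 0 rose. The median was -0.48 and the camera adjusted p = 6.0e-06, against an adjusted p = 0.748 with an estimated correlation. The list's mean log2 CPM in knockout replicate 3, 4.03, lay within the controls (3.39 to 4.29). The other knockouts lay at 2.54 to 3.03. In this list Mcpt8, a basophil protease, had 9.09 ± 3.11 and 4.80 ± 2.18 CPM.

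Receptors for blood cytokines held 1 changed member of 19 tested, Ifngr1, the interferon gamma receptor chain, which fell 2.05-fold from 121 ± 10 to 59.1 ± 8.3 CPM. Adjusted over the list alone, 5 fell and 0 rose. Kit, the receptor for stem cell factor, had 293 ± 24 CPM in the controls and 194 ± 24 CPM in the knockouts (adjusted p = 0.056), and Csf3r, the receptor for granulocyte colony-stimulating factor, 60.7 ± 22.1 and 26.5 ± 6.7 CPM (adjusted p = 0.095). The median was -0.23 and the camera adjusted p = 5.2e-06, against an adjusted p = 0.748 with an estimated correlation.

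Megakaryocyte and platelet genes had a median of -0.31 over 21 tested members, 17 of them lower. None passed over all genes (3 lower unadjusted, 2 lower by DESeq2) and 3 fell adjusted over the list alone. Ppbp, a platelet chemokine, had 196 ± 66 CPM in the controls and 62.9 ± 39.2 CPM in the knockouts. The camera adjusted p = 0.0016 became an adjusted p = 0.748 with an estimated correlation. It was 0.148 without knockout replicate 3, and 0.508 without control replicate 2, where the median was 0.034. In the dendritic cell and MHC class II list, 10 of 12 members were lower and 0 passed over all genes (1 lower unadjusted, 0 by DESeq2) or adjusted over the list alone (median -0.31, camera adjusted p = 0.047, adjusted p = 0.748 with an estimated correlation). That call was also lost without control replicate 2 (camera adjusted p = 0.372) and without knockout replicate 1 (0.208), 2 (0.067) or 4 (0.060).

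Among signalling groups, 16 of 18 interferon response genes were lower, with a median of -0.29, and 0 passed over all genes (2 lower unadjusted, 0 by DESeq2) or adjusted over the list alone. The camera adjusted p = 0.010 became an adjusted p = 0.748 with an estimated correlation, was 0.060 without knockout replicate 4, and was 0.561 without control replicate 3, where the median was 0.022. Of 20 immediate early genes, which respond to cell dissociation, 0 passed over all genes (6 lower unadjusted, 1 lower by DESeq2) and 1 fell adjusted over the list alone, with a median of -0.24 (camera adjusted p = 0.0042, adjusted p = 0.748 with an estimated correlation). Fos had 44.2 ± 8.7 CPM in the controls and 24.7 ± 5.1 CPM in the knockouts. Without control replicate 1 the immediate early median was 0.059 (camera adjusted p = 0.912). Of 17 homing and adhesion genes, 0 passed over all genes (3 lower unadjusted, 1 lower by DESeq2) and 1 fell adjusted over the list alone, with a median of -0.09 (camera adjusted p = 0.0095, adjusted p = 0.748 with an estimated correlation, and 0.056 without knockout replicate 1). Without control replicate 2 its median was 0.0019 (adjusted p = 0.497). Cd44, a member of the homing and adhesion list, had 149 ± 12 CPM over all controls and 120 ± 6 CPM over all knockouts.

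The lists that stood higher held no member that passed over all genes in edgeR. All 20 cholesterol synthesis genes were higher (8 unadjusted, 0 by DESeq2), with a median of 0.28; adjusted over the list alone 2 rose (camera adjusted p = 6.8e-08, adjusted p = 0.748 with an estimated correlation). The list's mean log2 CPM was 6.65, 6.23, 6.02 and 6.55 in knockout replicates 1 to 4. The controls held 6.06, 6.00 and 6.16. Fdps, which makes farnesyl pyrophosphate, had 122 ± 8 CPM in the controls and 154 ± 15 CPM in the knockouts. All 22 hepatocyte genes, which mark the liver cells around the blood progenitors, were higher with a median of 0.24, and 0 passed unadjusted, by DESeq2 or adjusted over the list alone (camera adjusted p = 0.0036, adjusted p = 0.748 with an estimated correlation). Afp, a serum protein of fetal hepatocytes, had 4051 ± 924 and 5934 ± 2192 CPM. As in cholesterol synthesis, knockout replicates 1 and 4 stood highest in the hepatocyte list. Their mean log2 CPM was 8.55 and 8.74, against 8.02 and 7.87 in the other knockouts. Those other knockouts lay within the controls (8.08, 7.65 and 8.41). The hepatocyte call was lost without control replicate 2 (camera adjusted p = 0.638) and without knockout replicate 4 (0.270).

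Erythroid genes moved in both directions. Of 26 tested, 0 passed over all genes in edgeR (7 higher and 2 lower unadjusted) and DESeq2 called 4 higher and 2 lower, while adjusted over the list alone 4 rose and 2 fell. Car1, a carbonic anhydrase of red cells, had 17.9 ± 1.8 CPM in the controls and 29.2 ± 6.2 CPM in the knockouts. The list median was 0.10 (camera adjusted p = 0.0090, adjusted p = 0.756 with an estimated correlation, and 0.123 without knockout replicate 3). Without control replicate 2 it was -0.054 (camera adjusted p = 0.638). Of 14 haem synthesis genes 11 were higher and 0 passed over all genes (2 higher unadjusted, 1 higher by DESeq2) or adjusted over the list alone (median 0.16, camera adjusted p = 0.0064, adjusted p = 0.748 with an estimated correlation). Alas2, the erythroid enzyme of the first step, had 16.1 ± 6.5 and 30.2 ± 3.1 CPM and was the member that DESeq2 called (adjusted p = 0.015). The haem call was lost without control replicate 2 (camera adjusted p = 0.508) and knockout replicate 3 (0.092). Of the 3 embryonic globins, 0 passed over all genes (1 higher and 1 lower unadjusted, 1 lower by DESeq2); adjusted over the list alone, Hbb-y fell and Hbb-bh1 rose, from 2.84 to 0.366 CPM and from 0.376 to 0.987 CPM. Their list did not pass camera with all libraries (adjusted p = 0.441, median -0.85) and passed as lower without control replicate 2 (adjusted p = 9.7e-04).

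Metabolic and growth lists also had small positive medians. They were 0.24 over 21 glycolysis and hypoxia genes (camera adjusted p = 6.7e-04, adjusted p = 0.748 with an estimated correlation), 0.25 over 17 integrated stress response genes (camera adjusted p = 0.0021, adjusted p = 0.748 with an estimated correlation) and 0.09 over 21 ribosome biogenesis genes (camera adjusted p = 0.014, adjusted p = 0.748 with an estimated correlation). No member of these 3 lists passed over all genes or adjusted over the list alone; 6, 7 and 1 were higher unadjusted, and DESeq2 called 1 integrated stress response gene higher. Eno1 had 792 ± 93 CPM in the controls and 1038 ± 162 CPM in the knockouts, and Mthfd2 59.5 ± 5.6 and 89.0 ± 23.6 CPM. The ribosome biogenesis call was lost without control replicate 2 (camera adjusted p = 0.243) or 3 (0.054) and without knockout replicate 1 (0.337).

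Genes of stem and multipotent progenitors did not stand apart from other genes. Of 22 tested, 11 were higher and 11 lower, 0 passed over all genes (3 higher and 2 lower unadjusted, 1 lower by DESeq2), and Kit alone fell adjusted over the list alone. Gata2 had 62.4 ± 22.7 CPM in the controls and 87.9 ± 13.3 CPM in the knockouts. The median was -0.0023 while camera pointed up (adjusted p = 0.658). Without control replicate 2 the median was 0.36 and the list passed as higher (camera adjusted p = 5.8e-04), as did the Hox and Meis list (0.58, adjusted p = 7.8e-04), which did not pass with all libraries (0.23 over 10 tested, adjusted p = 0.144, 0 members passing over all genes, unadjusted, by DESeq2 or adjusted over the list alone). The fetal stem cell programme had a median of 0.0087 over 13 genes (-0.0066 with scaling to total counts) while its mean was -0.040 and camera pointed down (adjusted p = 0.592). None of it passed over all genes (3 lower unadjusted, 1 lower by DESeq2), while 3 fell adjusted over the list alone, among them Hmga2, with 71.6 ± 25.2 CPM in the controls and 43.7 ± 3.3 CPM in the knockouts.

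The other SWI/SNF subunits, partners and relatives of Brd9, held 0 of 26 members passing over all genes (3 higher unadjusted, 2 higher by DESeq2). Adjusted over the list alone 2 rose, Gltscr1l, a subunit of the Brd9-containing complex (50.0 ± 1.6 to 67.4 ± 8.2 CPM), and Dpf1, a subunit of another BAF complex (3.13 ± 0.07 to 5.47 ± 1.07 CPM). The median was -0.0061 while camera pointed up (adjusted p = 0.514). CTCF and cohesin genes had a median of -0.041 over 11 members (camera adjusted p = 0.501), DNA replication genes 0.059 over 22 (adjusted p = 0.123), mitosis genes 0.027 over 20 (adjusted p = 0.658), p53 targets 0.071 over 20 (adjusted p = 0.380) and mitochondrially encoded genes -0.017 over 13 (adjusted p = 0.801). No member of these 5 lists passed over all genes, by DESeq2 or adjusted over the list alone; at an unadjusted p under 0.05 there were 1 CTCF and cohesin gene and 1 p53 target lower, and 1 DNA replication gene and 1 p53 target higher. Only the DNA replication list passed when libraries were left out, as higher without control replicate 1 (adjusted p = 0.021) or knockout replicate 4 (adjusted p = 0.0076).

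Markers of other cell types were also measured. Of 17 endothelial genes 0 passed over all genes (3 lower unadjusted, 1 lower by DESeq2) and Cdh5, a junction protein, fell adjusted over the list alone, from 18.3 ± 0.5 to 10.4 ± 2.3 CPM. The endothelial median was -0.20 (camera adjusted p = 0.054), and the list passed as lower without control replicate 1 (adjusted p = 0.0021) or 3 (0.013) and without knockout replicate 4 (0.013). Of 15 NF-kB and inflammation genes 0 passed over all genes (3 lower unadjusted, 1 lower by DESeq2) and 1 fell adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.053), and the list passed as lower without control replicate 3 (adjusted p = 0.0027) or knockout replicate 3 (0.026). Of 17 stromal and stellate genes 0 passed over all genes (1 lower unadjusted, 1 lower by DESeq2) and 1 fell adjusted over the list alone (median 0.32, camera adjusted p = 0.562). No gene of the lymphoid lists passed over all genes. Of 12 lymphoid-primed progenitor genes (1 higher and 2 lower unadjusted, 1 lower by DESeq2) 2 fell adjusted over the list alone (median -0.073, camera adjusted p = 0.398, and 0.016 as lower without knockout replicate 3), and of 5 B lineage genes 0 passed unadjusted, by DESeq2 or adjusted over the list alone (median 0.31, adjusted p = 0.658).

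Of 12 T, NK and innate lymphoid genes, 0 passed over all genes (4 higher and 1 lower unadjusted, 1 higher and 1 lower by DESeq2); adjusted over the list alone, Tcf7 rose and Nkg7 fell. The median was 0.49 (camera adjusted p = 0.171), and the list passed as higher without knockout replicate 1 (adjusted p = 0.011) or 2 (0.049). Knockout replicate 3 stood apart in this list. It held 18.2 CPM of Cd3g, a T cell receptor chain, and 17.2 CPM of Tcf7, where no other library held above 1.02 CPM of Cd3g or 5.84 CPM of Tcf7. Tcf7 was also higher in the other knockouts (5.84, 3.83 and 5.65 CPM) than in the controls (2.49, 2.40 and 2.43 CPM). Without that library the test of all genes gave 120 calls, 116 lower.

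**Figure D3:**
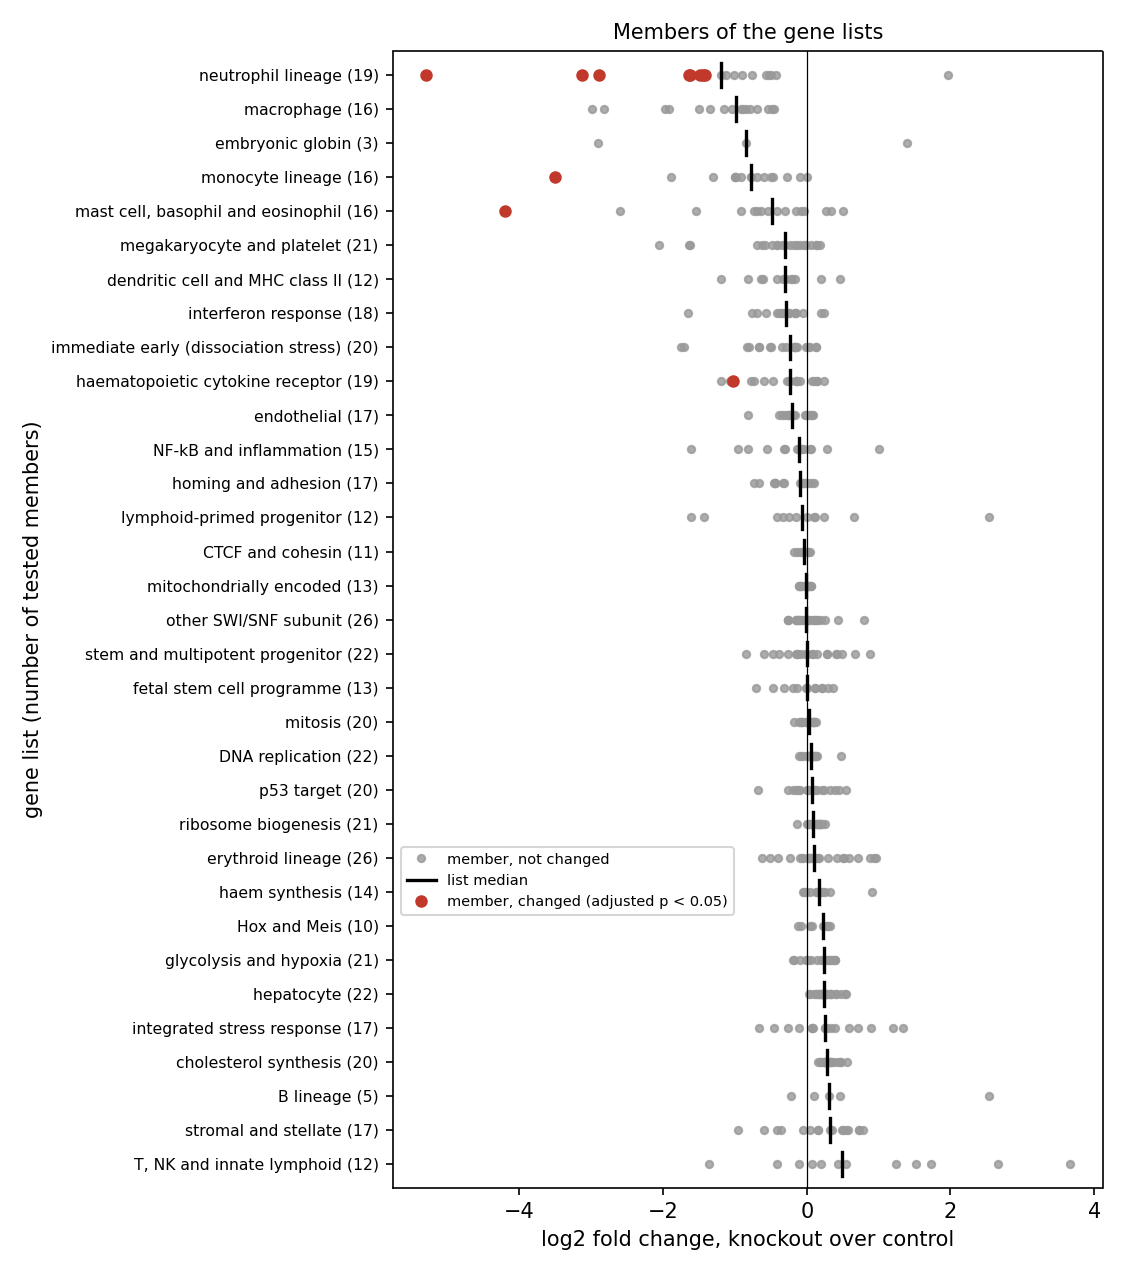
Log2 fold change of each tested member of the 33 gene lists, knockout over control, with lists ordered by their median (black bar) and the number of tested members in parentheses. Red points are members at an adjusted p under 0.05 over all genes. The 11 red points lie in 4 lists (neutrophil, monocyte, mast cell with basophil and eosinophil, and cytokine receptor), all below 0.

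With camera's preset correlation 17 of the 33 lists passed, 7 higher and 10 lower, and with an estimated correlation 0 passed, the lowest adjusted p being 0.493 and 2 lists having an unadjusted p under 0.05. The estimates ran from 0.0019 (p53 target) to 0.926 (megakaryocyte and platelet), against the preset 0.01. By fry, 0 passed for a shared direction (lowest adjusted p = 0.280, 3 lists at an unadjusted p under 0.05). For change in either direction 5 passed by fry. They were the neutrophil, monocyte, mast cell with basophil and eosinophil, cytokine receptor and p53 target lists (p53 target adjusted p = 0.015). Fry does not compare members with other genes. Of 20 p53 targets only 1 was higher and 1 lower at an unadjusted p under 0.05, beside 1593 of all 14679 tested genes. Camera, which does compare them, gave that list an adjusted p = 0.380. In the exact permutation test of list means no list reached the smallest possible p of 0.0286, and the neutrophil, monocyte and macrophage lists each gave p = 0.0571. In each of these lists every knockout mean lay below every control mean, but another split gave at least as large a difference. Other settings also moved camera calls. With the replicate block, knockout replicate 4 left out, the hepatocyte (camera adjusted p = 0.228), interferon response (0.180) and dendritic cell (0.052) lists did not pass. The DNA replication (0.0067) and endothelial (0.026) lists passed there. With the Xist level as a covariate, chosen after the data were seen because the groups differed in their mix of embryo sex, the interferon response (adjusted p = 0.236) and immediate early (0.140) lists no longer passed, while the endothelial (0.0045), DNA replication (0.016) and NF-kB (0.029) lists did. With 1 surrogate variable the dendritic cell (0.178), hepatocyte (0.078) and ribosome biogenesis (0.102) lists did not pass and the T, NK and innate lymphoid list (0.0052) did, and at a minimum mean of 1 CPM the dendritic cell list (0.132) did not.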

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

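In the group of 4 knockout libraries, 195 quantities were searched for a library far from the others, and 8 had a gap to the nearest library, as a share of the whole range, above Dixon's 95% critical value. Chance flags about 1 in 20, which would be 9.8 here. The test of T cell genes outside the lists, the comparison of libraries with like Xist and the test of an effect shared by all knockouts were set out before their results were seen; all other tests in this part were chosen after. Knockout replicate 3 was high in the B lineage list (gap 0.856 of the range, mean log2 CPM 1.74 against -0.31 to -0.013), in Thy1 (0.905, log2 CPM 3.71 against -0.20 to 0.18) and in Prss57 (0.857, 2.86 against 2.10 to 2.21, where the control mean was 4.86). In the B lineage list its Rag1 stood at 16.1 CPM, against 0.33 to 0.97 in the other knockouts. Its Spib and Cd72 were also the highest, while its Cd79b was not (7.05 CPM against 3.87 to 7.26). Knockout replicate 1 was high in Psat1 (0.921, 8.80 against 8.22 to 8.26) and low in Il6 (0.888, -1.07 against 0.094 to 0.24) and Gata2 (0.888, 6.09 against 6.53 to 6.59). Knockout replicate 4 was low in Nfkbia (0.918, 4.88 against 5.29 to 5.33) and high in Acta2 (0.873, 1.03 against -0.23 to -0.073).

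The neutrophil list stood low in the knockouts, with 8 of its members among the 82 changed genes but adjusted p = 0.493 with an estimated correlation and p = 0.0571 in the exact permutation test of its mean. For the count of all changed genes, not for this list, 1 of the 35 splits into 3 and 4 libraries, the real one, gave as many as 82. The highest other, which parts high from low Xist, gave 6. The smallest p that 35 splits can give is 0.0286, and the other splits hold the group difference within their spread. That argues against chance for the count but does not exclude it. More red-cell or liver-cell RNA diluting everything else is argued against. The stem and multipotent progenitor list had a median log2 fold change of -0.0023 (95% bootstrap interval over 22 genes -0.13 to 0.21). The neutrophil list had -1.19 (-1.58 to -0.77). Embryo sex as the whole source is argued against too. With the Xist level as a covariate the neutrophil median was -1.30 (-1.75 to -0.95) and 8 of 19 members were called lower. Comparisons of libraries with like Xist (medians -1.64 and -1.14) had 1 control or 1 knockout library and decide nothing alone. The bootstrap intervals, here and below, draw genes as if independent and do not measure the spread between libraries. Over left-out libraries the stem and multipotent progenitor median ran from -0.15 to 0.36. A loss of neutrophil-lineage cells by 1 common factor would lower all members alike, but Cochran's Q of their fold changes was 10.9 per degree of freedom (19 genes), where 1 common factor gives about 1. Fewer granulocyte precursors whose genes other cells also express, less mature precursors, and lower transcription per cell stay open, because bulk libraries do not count cells; that Brd9 loss lowers this programme remains a hypothesis.

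T cell transcripts stood high in knockout replicate 3, where 7 of the 12 tested T, NK and innate lymphoid genes were highest, among them Cd3g at 18.2, Tcf7 at 17.2 and Lck at 14.7 CPM. Of 12 other T cell genes in no list, with at least 10 reads in all, 6 were highest there (exact binomial p against 1 in 7 = 0.0036, one-sided, with genes taken as independent, which they are not). T-lineage cells or tissue in this library may be the source, although the lineage depletion is meant to remove mature T cells. Tcf7 also stood above every control in each other knockout library. An effect shared by all 4 knockouts was not decided: over the list, the other 3 knockout libraries lay 0.30 above the controls on the log2 scale (95% bootstrap interval -0.20 to 0.58) and this library 0.86 (-0.098 to 2.80). The gene calls do not rest on it, with 76 of the 82 among the 120 found without it.

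Sva, which had reads in every knockout library and no control, was asked whether its whole region was active. The 8 tested genes within 1 Mb had a median log2 fold change of 0.064 (95% bootstrap interval -0.094 to 0.31), and their lowest unadjusted p was 0.085, which argues against it. An inserted sequence near Sva that comes with the knockout genotype and a direct effect of Brd9 loss were not tested and stay open.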

How the results depend on the processing

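The Xist covariate and the permutation of list means were added after the data were seen; all other settings were planned. Brd9 was called lower in each setting, with log2 fold changes of -1.42 to -1.60. Counts of genes stayed within 1.5 times of 82 with DESeq2 size factors (83), total counts (83), a minimum of 1 CPM (76), limma-voom (74), robust dispersion (87), Xist, Tsix and the Y-linked genes left out (85) and the Xist covariate (55, 51 of them shared). Higher genes numbered 1 at the minimum of 1 CPM, which removes Sva, and 1 with the Xist covariate. With no filter 228 genes changed (12 higher, 216 lower), with DESeq2 386 (56 and 330, of which 382 are in the authors' table) and with 1 surrogate variable 141 (9 and 132); each of these sets but the last holds all 82, and that one 81. The cause was not tested. Leaving out single libraries gave 20 to 120 genes, 1 to 4 higher and 19 to 116 lower: 96, 49 and 20 without control replicate 1, 2 and 3, and 51, 21, 120 and 37 without knockout replicate 1 to 4. Fewer samples lower the power, and 19 of the 82 genes were called in all 7 of these fits, among them Brd9, Serpinb10, Camp, Epx, F13a1, Nebl, Stfa3, Elane, Ifngr1 and Sva. Deviations of same-numbered libraries correlated at 0.17, -0.022 and -0.0052, which showed no clear pairing but cannot exclude it. The fit with the replicate block, knockout replicate 4 left out, gave 126 genes (5 higher, 121 lower, 63 shared). The same libraries without the block gave 37. Sva, Kcna2, Tlr4 and Msr1 were not among the 126. Over 18 settings the 34 named genes that were called gave 520 results past the threshold, 91 short of it and 0 in the other direction. Between 13 and 18 lists passed in the fits that ran camera with the preset correlation, and 0 with an estimated correlation, 0 by fry and 0 in the permutation test.

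Medians of lists that turned sign, the cause not tested, were these. Fetal stem cell programme -0.0066 with total counts, -0.020 with the replicate block, -0.083 with the Xist covariate and -0.079 to 0.11 over left-out libraries. Stem and multipotent progenitor 0.00039 at the minimum of 1 CPM, 0.011 with the block, 0.13 with the surrogate variable and -0.15 to 0.36 over left-out libraries. Lymphoid-primed progenitor was 0.0073 at the minimum of 1 CPM, 0.048 with the surrogate variable and -0.30 to 0.29 over left-out libraries. Other SWI/SNF subunits were at 0.0075 with the block, 0.0032 with the surrogate variable, 5.4e-05 with the Xist covariate and -0.022 to 0.015 over left-out libraries. With the Xist covariate CTCF and cohesin was at 0.00017 and mitochondrially encoded genes at 0.0023. Over left-out libraries the ranges were -0.10 to 0.070 for mitochondrially encoded genes, -0.44 to 0.059 for immediate early, -0.00036 to 0.11 for DNA replication, -0.33 to 0.056 for endothelial, -0.054 to 0.21 for erythroid, -0.23 to 0.0019 for homing and adhesion, -0.47 to 0.034 for megakaryocyte and platelet, -0.0075 to 0.58 for Hox and Meis, -0.42 to 0.022 for interferon response, -0.31 to 0.50 for B lineage and -0.011 to 0.055 for mitosis. The uncalled genes that turned were Spib (-0.31 with limma-voom), Rag1 (-0.38 to 2.92), Cd79b (-0.40 to 0.060) and ND5 (-0.17 to 0.014). Depth limits low genes most: 3 counts in a library stand for 0.12 to 0.16 CPM.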

Other observations

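Genes outside the lists that also fell, chosen after their values were seen, include these 7. Tlr4, the receptor for bacterial lipopolysaccharide, fell from 9.37 ± 0.15 to 3.90 ± 0.76 CPM, and C5ar1, the receptor for complement fragment C5a, from 3.65 ± 0.46 to 1.11 ± 0.06 CPM. The inhibitory receptor Lair1 fell from 5.14 ± 0.67 to 1.28 ± 0.35 CPM (SD, n = 3 and 4). The scavenger receptors Olr1 and Msr1 and the lectin Mgl2 fell with log2 fold changes of -1.34, -1.64 and -3.10 (edgeR adjusted p = 0.013, 0.0497 and 0.013). Casp1, a protease that processes interleukin 1, fell by 1.45 on the log2 scale. All 7 of these genes, Tlr4, C5ar1, Lair1, Olr1, Msr1, Mgl2 and Casp1, lost their calls without control replicate 3 or knockout replicate 2. Other libraries also ended calls when left out: control replicate 1 for Tlr4 and Msr1, control replicate 2 for Tlr4, Msr1 and Casp1, knockout replicate 1 for Olr1, Msr1 and Casp1, knockout replicate 3 for Msr1, and knockout replicate 4 for Tlr4, Olr1, Msr1, Mgl2 and Casp1. With the Xist level as a covariate Tlr4 (adjusted p = 0.067) and Msr1 (0.159) lost their calls, with limma-voom Msr1 (0.071) and Casp1 (0.052), and at a minimum mean of 1 CPM Msr1 (0.053).

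Alas1, the housekeeping enzyme of the first step of haem synthesis, fell from 130 ± 27 to 64.5 ± 4.7 CPM (edgeR adjusted p = 0.010). Prss57, a serine protease of neutrophil granules that the list had left out, fell by 2.56 on the log2 scale, and Hk3, a hexokinase of myeloid cells, by 1.94. Alas1 and Hk3 lost their calls without control replicate 3 or knockout replicate 2, and Hk3 also without control replicate 2 or knockout replicate 4 and with the Xist level as a covariate (adjusted p = 0.090).

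Neutrophil granules form in order, and the hypothesis that genes of late granules fell more than those of early, azurophil granules was tested after the values had been seen. The mean log2 fold change was -1.35 over the late genes (Camp, Ltf, Ngp, Lcn2, Mmp8, Mmp9 and Fcnb) and -1.86 over the azurophil genes (Mpo, Elane, Prtn3 and Ctsg), and -1.86 and -2.07 in the same order without knockout replicate 3, in which Ltf, Lcn2 and Ngp were highest among the knockouts. The exact permutation test over the 330 ways to divide the 11 genes gave p = 0.679, and 0.848 without that library, two-sided, with genes not independent of each other, so the order was not decided. Within the late genes the values ran from -5.31 for Camp to -0.53 for Ltf, -0.42 for Lcn2 and 1.97 for Mmp8.

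Xist, the transcript of the inactive X chromosome, stood at 756 and 802 CPM in control replicates 1 and 3 and 739 CPM in knockout replicate 2, and at 0.37 CPM or less in the other libraries. Those libraries held 62.3 to 82.8 CPM of the Y-linked Ddx3y, and the 3 with high Xist held none. The groups thus differed in their mix of embryo sex, which the labels do not give.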
